A study of Caenorhabditis elegans with 2 samples.

How the data were processed

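The measurements were chromatin immunoprecipitation sequencing profiles of MXL-3 fused to EGFP and FLAG in whole L4 larvae of Caenorhabditis elegans, aged 48 hours, made from 2 biological replicates of 1 group with an anti-GFP antibody, per the labels. The larvae had been synchronised by bleaching and starvation at the first larval stage, and chromatin was fragmented by sonication to between 200 and 800 bp, per the labels. The labels give the replicates as separate biological replicates.

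The authors deposited narrowPeak lists on assembly ce11, which carries the sequence of WBcel235. Per the listings deposited with each replicate, a peak list was made from each replicate's alignments and a control, a pooled list from both replicates' alignments and a control, and the IDR-thresholded list from the pooled list. The peak caller, the aligner and the strain of the control are not given in the sources used here. For each peak the deposited lists give a signal value from the authors' peak caller on a scale that the sources used here do not define, and it was used to describe, rank or select peaks within its own list and, for the correlation and plot of the replicates, to set the values of matched peaks in the replicate lists against each other. The lists also hold a column that the authors gave as the −log10 of the caller's q-value, which ran from 2.21 to 3.67 in the IDR list and was used only to order ties. The replicate and pooled lists had 30000 peaks each, background included, so their length carries no information on binding. All 3935 IDR peaks were in the pooled list, and they were its 3935 highest by signal. The files hold no IDR values, so the planned tie-break on IDR was not used.

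Read counts were not used here, so the depth behind each peak is unknown. Intervals on shares are exact Clopper-Pearson intervals at 95% over peaks or genes. They cover counting error only and treat peaks as independent. The signal value carries no error of its own.

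Peak coordinates were compared with the lengths of the 6 nuclear chromosomes of the RefSeq WBcel235 sequence and lay within them, and gene models came from Ensembl release 115. Positions are 1-based. The promoter window ran from 1000 bp upstream to 200 bp downstream of every annotated start of a protein-coding gene, and a gene was bound where an IDR summit lay in it. Motifs were searched on both strands within 100 bp of the summit and in an equal window 500 bp away, on a side drawn with a fixed seed. Summits within 100 bp counted as shared between replicates. The location of a summit was taken in the order coding sequence, 5' UTR, 3' UTR, other exon, intron and intergenic.

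The replicate overlap was tested by a 1-sided permutation test with 100000 draws, for which the smallest p is 1e-05. The promoter share and the small RNA genes were tested by 1-sided random placement tests with as many draws. These drew binomial counts per chromosome, so peaks were taken as independent and their clustering was not kept. CACGTG and the 10 E-box classes were tested with the exact McNemar test, strong against weak peaks and the base before CACGTG with Fisher's exact test, the X share with the exact binomial test and gene lists with Fisher's exact test, all two-sided, with Benjamini-Hochberg adjustment over the E-boxes and over the 24 lists and a threshold of 0.05. The interval of Spearman's rho came from 1000 bootstrap resamples of peaks. Of the names in the lists 4 matched no protein-coding gene symbol, 2 of them in the stress response list (hsp-16.11 and hsp-16.49, whose genes carry a shared symbol in the annotation), and the others were atg-11 and ram-4. The lists, tests and rule for named genes were fixed before the data were examined. That rule named mxl-3 and unc-119, the genes with any of the 20 strongest IDR summits in their promoter window or else the nearest start, up to 4 bound members of each list by signal, and all members of the Max network and lysosomal lipase lists.

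On 20 simulated sets of 3935 uniformly placed peaks the promoter test passed its threshold in 3, and in 400 further sets in 22 (5.50%). In the 20 sets the CACGTG test passed in 0, the E-box tests in 0 and the gene list tests in 2 of 480. Uniform placement gives no difference in base composition between summit and flank, unlike the IDR peaks. The simulated motif tests therefore do not cover calls that come from composition. A planted CACGTG excess of 10.2% was recovered as 10.3%, with 1 of the other E-boxes also called, and planted sharing of 60% of peaks as 60.3%. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

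Alternatives were a stricter peak set, each replicate alone, the pooled list, other summit distances, other peak numbers, other promoter and motif windows, other controls for the motif, assignment to the nearest start within 2000 bp, and peaks with or without CACGTG. Peak sets without the mxl-3 locus or small RNA genes, the rotation test, the most upstream start per gene and the pooled peaks below the threshold were added after the data were seen. Coverage tracks and alignments were not analysed here.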

Results

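The data were genome-wide binding profiles of MXL-3, a basic helix-loop-helix leucine zipper transcription factor of the Max family, in Caenorhabditis elegans. Whole L4 larvae of mixed sex, 48 hours old, carried a transgene with mxl-3 fused to EGFP and FLAG tags together with an unc-119 rescue marker. Chromatin was sonicated and immunoprecipitated with an anti-GFP antibody in 2 biological replicates of 1 group, so the comparisons set bound against unbound positions within the genome and not one condition against another. Each replicate list and the pooled list held 30000 peaks including background. The list that passed the authors' irreproducible discovery rate (IDR) threshold held 3935 peaks, with a median width of 376 bp, and covered 1371848 bp. No read totals were used here, so the sequencing depth behind each peak is unknown. The value given for a peak is the authors' own signal value, which ranks peaks within its list, and it ran from 91.1 to 1445 in the IDR list.

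The strongest MXL-3 sites lay in the same places in both replicates. The peak upstream of nhr-68, a nuclear hormone receptor gene, ranked 2 in replicate 1 and 1 in replicate 2, and the peak at gst-20, a glutathione S-transferase gene, ranked 3 and 2. Of the 3935 highest-ranked peaks of replicate 1, 2795 (71.0%, exact 95% interval 69.6 to 72.4%) had a summit within 100 bp of a summit among the 3935 highest-ranked peaks of replicate 2. Peaks drawn at random from the full lists shared 5.75% on average and at most 7.50% in 100000 draws (one-sided permutation p = 1e-05, the smallest the draws can give). A peak in each replicate list was found for 3795 IDR peaks, and 140 lacked one in at least 1 list. Across those peaks, which are not independent replicates, Spearman's rho of the signal values was 0.709 (bootstrap 95% interval 0.689 to 0.730) and Pearson's r of their log2 values was 0.800. These peaks had been selected by the authors' threshold on reproducibility and are the highest of the pooled list, so the correlation describes the selected peaks and is not a test of whether the replicates matched. No interval was identical between the replicate lists.

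**Figure D1:**
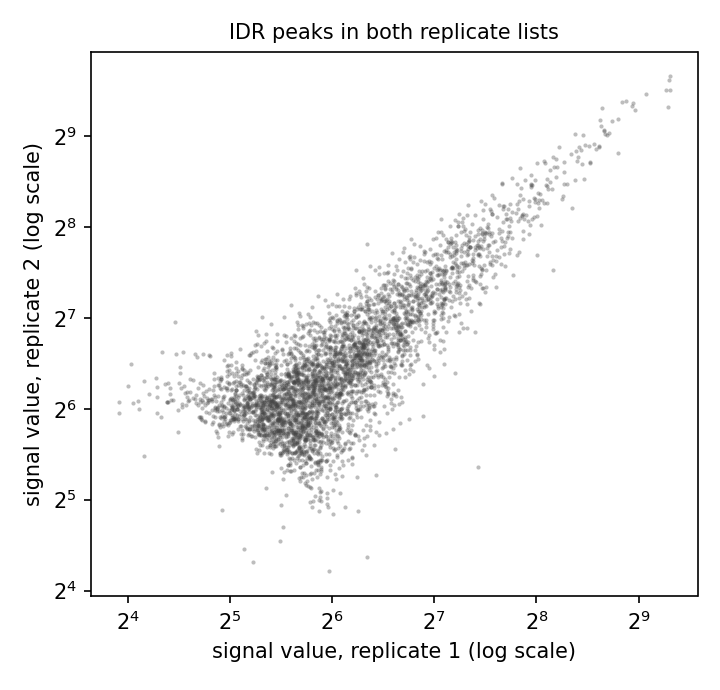
Signal value of each IDR peak found in both replicate lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales, with 1 point per peak. The 3795 points rise together at high signal and scatter widely at low signal, with Spearman's rho of 0.709. At the 20 strongest peaks the replicate 2 value was above that of replicate 1.

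Of the 20 strongest peaks 17 stood at promoters, led by those of nhr-68 and gst-20. The first, with a signal value of 1445, had its summit at position 11573044 of chromosome V (peak 11572842 to 11573252, WBcel235), in intergenic sequence at -396 bp from the start of nhr-68 (WBGene00003658) and -54 bp from the divergent gene H12C20.7. The peak at gst-20 (WBGene00001768) had its summit on II at 13609846, in intergenic sequence at -22 bp, with a signal of 1408. Peaks with signals of 1339 and 1264 lay at -326 bp from sucl-1 on X (summit 14753700) and at -137 bp from met-1, a histone H3 lysine methyltransferase gene, on I (summit 4254060). A single intergenic peak on IV (summit 11119213, signal 1236) stood at -85 bp from enpl-1, which encodes the endoplasmic reticulum chaperone endoplasmin, and at -326 bp from imp-2, which encodes an intramembrane protease.

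Other genes with 1 of the 20 strongest summits in their promoter window were iff-2, a translation factor gene of the eIF-5A family, at -78 bp with a signal of 1141, serp-1.1 at -265 bp with 1125, mans-3 at -179 bp with 1119 and tasp-1 at -37 bp with 1111. The summit near iff-2 also lay at -857 bp from F54C9.14, and that near tasp-1 at -748 bp from K01G5.10. They were followed by adh-1 at -99 bp with 1029, dpsm-1 at -307 bp with 1026 and sym-4 at -214 bp with 996. C05C10.3 had its summit at -915 bp with 973, and the protein disulfide isomerase gene pdi-3 and the ubiquilin gene ubql-1 shared a summit at -636 and -539 bp with 960. The remaining promoter summits belonged to the phosphatase gene ppm-2 at -997 bp with 952, K02A6.3 at -67 bp with 935 and the receptor gene nhr-35 at -380 bp with 930. Of the 20 peaks, 10 had a CACGTG hexamer within 100 bp of the summit and 8 were on X. All ranked 22 or higher in replicate 1 and 20 or higher in replicate 2.

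The other 3 of these peaks lay outside promoter windows, 2 of them beside mxl-3 itself. The third strongest (summit 13355195 on X, signal 1372) was intergenic at -4391 bp from the mxl-3 start, and the seventh (summit 13358689, signal 1150) was intergenic between mxl-3 and C49F8.15, at 3897 bp downstream of the start of C49F8.15. The last lay in an intron on II (summit 9601319, signal 934), with the start of mrpl-53 as the nearest at 3697 bp. The mxl-3 gene (WBGene00003511, X, 13349639 to 13350804, minus strand) also had a promoter summit at 13351073, -269 bp from its start, with a signal of 489 and rank 121. Within 20 kb of the gene lay 20 IDR summits, from 13334092 to 13369428, where the average density of X would give 2.24. The rescue marker gene unc-119 (III, 10902641 to 10908935) had no IDR summit in its promoter window or within 50 kb. The transgene holds a further copy of mxl-3, and the files do not separate its signal from that of the endogenous locus.

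**Figure D2:**
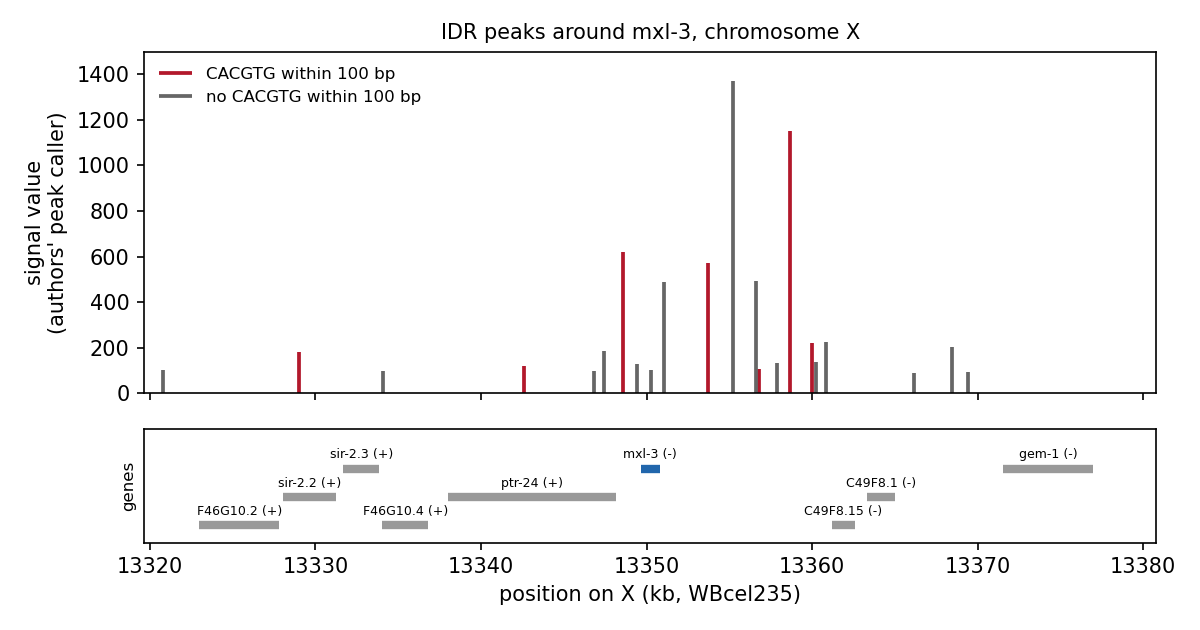
IDR peaks around mxl-3 on chromosome X. Each vertical line stands at a summit (x axis, position in kb on WBcel235) with its height the authors' signal value, in red where CACGTG lay within 100 bp and grey where it did not, and the lower panel shows protein-coding genes with their strand. The tallest lines, at 1372 and 1150, stand upstream of mxl-3, which reads from right to left.

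MXL-3 peaks favoured promoters. Of the 3935 IDR summits, 1993 (50.6%, exact 95% interval 49.1 to 52.2%) lay between 1000 bp upstream and 200 bp downstream of an annotated start of a protein-coding gene, against 25.8% of random positions on the same chromosomes and at most 29.0% in any of 100000 draws (one-sided permutation p = 1e-05, the smallest the draws can give). Intergenic sequence held 64.2% of summits and 37.3% of the nuclear genome, and 5' UTRs held 4.57% and 1.43%. Coding sequence held 3.66% of summits and 24.6% of the genome, introns 26.4% and 33.1%, and 3' UTRs 1.12% and 3.32%. The median distance of a summit from the nearest start was 751 bp, and 982 summits (24.96%) lay more than 2000 bp away. In all, 2259 of 19973 protein-coding genes (11.3%) had a promoter summit, and 399 peaks were counted at more than 1 gene.

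The E-box CACGTG, the hexamer that Max-family factors are known to bind, marked a minority of peaks. It lay within 100 bp of 625 of the 3935 summits (15.9%, exact 95% interval 14.8 to 17.1%) and in 132 (3.35%) of equal windows centred 500 bp away. In 604 peaks it was at the summit alone and in 111 at the flank alone (exact McNemar test, two-sided, p = 6.6e-83). Sites within 100 bp of a summit had a median distance of 30 bp from it. Summits without CACGTG included those at sucl-1, iff-2, serp-1.1, tasp-1 and nhr-35.

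CACATG and CAAGTG were the next most enriched E-boxes, at 17.3% of summits against 6.66% of flanks and at 12.1% against 6.68%. Of the 10 E-box classes 6 were higher at summits after Benjamini-Hochberg adjustment, the others being CACCTG, CAGCTG and CAACTG at ratios of 1.46, 1.33 and 1.27. Summit windows held 44.8% G or C and flank windows 34.9%, and composition alone moves the share of a hexamer. Against hexamers with the same bases, a comparison chosen after the data were seen, CACGTG had the highest summit to flank ratio, 4.73, where the other 101 had a median of 1.36 and a maximum of 3.04. Some hexamers with other bases but as much G and C exceeded it, such as GACGCA at 5.54. By p, CACGTG ranked 17 among the 966 hexamers higher at summits. Among hexamers with their own bases, 1 of 179 others had a higher ratio than CACATG and 3 of 179 a higher ratio than CAAGTG. The ratios of CACCTG and CAGCTG were near the medians of their classes, 1.43 and 1.36, while CAACTG was above its class median of 1.04, with 56 of 179 others higher. CACCTG and CAGCTG were no longer called without replicate 1 (4 classes called), CACCTG without the peaks near mxl-3 (5 called) and CAACTG with a window of 50 bp (5 called). CAAATG, CAATTG, CAGATG and CATATG did not pass the test (adjusted exact p from 0.137 for CAGATG to 0.454 for CAATTG), though CAGATG did with a window of 200 bp and without the peaks near small RNA genes (7 classes called in each). Leaving out the peaks near mxl-3 or small RNA genes also drew flank sides of the remaining peaks anew. Changes in call there therefore cannot be put down to the peaks left out.

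Strong peaks carried CACGTG more often than weak ones. It was present at 251 of the 983 peaks with the highest signal (25.5%, 22.8 to 28.4%) and at 107 of the 983 with the lowest (10.9%, 9.01 to 13.0%), an odds ratio of 2.81 (Fisher's exact test, two-sided, p = 2.8e-17). In the 500 strongest peaks the share was 28.4%. Among CACGTG sites at summits, 254 of 680 (37.4%, 33.7 to 41.1%) were read with T before the hexamer on at least 1 strand, against 44.4% of 126 flank sites and 40.02% of 16923 other sites. Neither comparison passed the threshold (Fisher's exact test, two-sided, p = 0.136 and 0.175). The test against other sites did pass with a window of 50 bp (32.5%, exact p = 0.00094), in the stronger of 2 equal parts of the peaks (35.01%, exact p = 0.0335) and without replicate 2 (36%, exact p = 0.0334), though not without replicate 1 (36.6%, exact p = 0.0828).

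**Figure D3:**
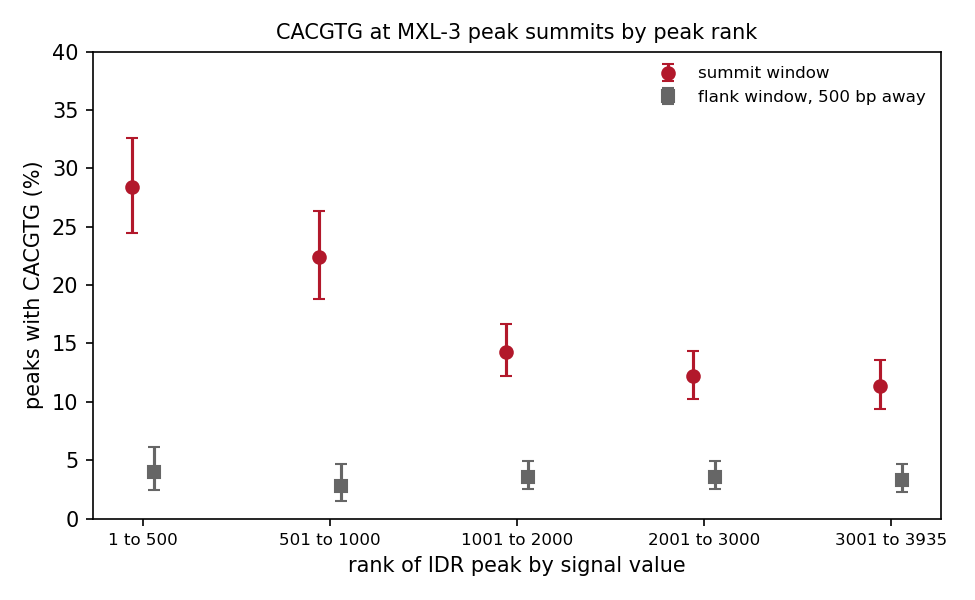
Percentage of IDR peaks with CACGTG within 100 bp of the summit (circles) and in a window 500 bp away (squares), by rank of the peak's signal value on the x axis, with exact 95% intervals as bars. The summit share falls from 28.4% in the 500 strongest peaks to 11.3% in the weakest group, and the flank share stays between 2.80% and 4%.

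The X chromosome held more peaks than its length predicts, among them the strong sites at sucl-1, serp-1.1, mans-3, sym-4 and nhr-35. It carried 964 of the 3935 IDR summits (24.5%, exact 95% interval 23.2 to 25.9%) and 17.7% of the nuclear genome length (exact binomial test, two-sided, p = 6.7e-27). Its share of protein-coding genes was 13.7% (exact binomial p = 2.3e-73). X had 54.4 peaks per Mb, while V had the lowest density, 31.5, and III the highest autosomal density, 42.5. Neighbouring peaks are not independent, which these p-values leave out.

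Genes listed under the Max network, autophagy, lysosomes, fat metabolism, stress responses, cytosolic ribosomes, nuclear hormone receptors and body wall muscle held promoter peaks more often than other genes. Of 24 gene lists fixed before the data were examined, 9 passed Fisher's exact test (two-sided, Benjamini-Hochberg over the lists) with more members bound, and 0 with fewer. In the list named Max network, which by its design also held hlh-30, 4 of 6 genes had a promoter peak (66.7%, 22.3 to 95.7%, against 11.3% of other genes, adjusted exact p = 0.0061). They were mdl-1, a Mad-like repressor gene (signal 548, rank 91), mxl-3 itself (489), hlh-30, the TFEB orthologue that controls lysosomal and autophagy genes (381, rank 239), and mml-1, a Mondo-like factor gene (187, rank 1129). The hlh-30 summit was in an intron at IV 4028387, -260 bp from an internal start, and mxl-1 and mxl-2 had no IDR promoter summit. Without the peaks within 20 kb of mxl-3, an alternative added after the data were seen, the call was lost, with 3 of 6 bound (50%, adjusted exact p = 0.0591, in a range of 0.0021 to 0.328 over its 13 alternatives).

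Lysosome-related genes were bound across several lists. Among autophagy genes 11 of 27 had a promoter peak (40.7%, 22.4 to 61.2%, adjusted exact p = 0.00059), led by the Atg8 homologues lgg-1 (signal 526) and lgg-2 (253) together with atg-16.2 (329) and atg-9 (250). Vacuolar ATPase subunits, which acidify lysosomes, had peaks at 8 of 21 genes (38.1%, 18.1 to 61.6%, adjusted exact p = 0.0047), with vha-13 (427), vha-8 (330), vha-1 (274) and vha-12 (272) the strongest, and none of their 8 peaks held CACGTG. The vha-8 summit, at -427 bp, lay nearer to the start of C17H12.2, at -159 bp. That of vha-13, at -557 bp, lay in a 3' UTR. With each peak assigned to its nearest start within 2000 bp, in place of the promoter window, the vacuolar ATPase call ended (28.6%, adjusted exact p = 0.0745). The list of lysosomal enzymes and membrane proteins had peaks at 10 of 35 genes (28.6%, 14.6 to 46.3%, adjusted exact p = 0.0115). Among them were cln-3.1 (236), the acid ceramidase gene asah-1 (235.2) and the LAMP homologue lmp-1 (198). The strongest was the intramembrane protease gene imp-2 (1236), whose summit lay nearer to the start of the endoplasmin gene enpl-1. The call for this list ended in the stronger of 2 equal parts of the IDR list (14.3%, adjusted exact p = 0.122) and with peaks without CACGTG alone (20%, adjusted exact p = 0.186). The lysosomal lipases did not pass the test, at 3 of 8 (37.5%, 8.52 to 75.5%, adjusted exact p = 0.122). Peaks at lipl-5 (248, -39 bp), lipl-1 (145, -82 bp) and lipl-2 (116, -30 bp) ranked 658, 1814 and 2646, those of lipl-5 and lipl-2 with CACGTG, and lipl-3, lipl-4, lipl-6, lipl-7 and lipl-8 had no IDR promoter summit.

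Fat metabolism genes were bound at 14 of 41 (34.1%, 20.1 to 50.6%, adjusted exact p = 0.00059), and at 8 of 41 (19.5%, adjusted exact p = 0.0504) with a promoter window of 500 bp upstream to 100 bp downstream, which ended the call. The strongest were the carnitine palmitoyltransferase genes cpt-2 (signal 318) and cpt-4 (316), the receptor gene nhr-49 (227), known for its control of fat breakdown, and the acyl-CoA oxidase gene acox-1.1 (168). Stress response genes were bound at 16 of 34 (47.1%, 29.8 to 64.9%, adjusted exact p = 2.4e-06). Their strongest members belong to the endoplasmic reticulum stress response, namely xbp-1 (485), the BiP homologue hsp-3 (426), the kinase gene pek-1 (310) and atf-6 (211). Near-identical copies in the hsp-16 family and the histones cannot be separated with certainty. Nuclear hormone receptors were bound at 49 of 274 (17.9%, 13.5 to 22.9%, adjusted exact p = 0.0042), led by nhr-68 (1445), nhr-35 (930), nhr-114 (494) and nhr-1 (349.5).

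Cytosolic ribosomal protein genes gave the smallest p of any list, with 34 of 79 bound (43.0%, 31.9 to 54.7%, adjusted exact p = 1.8e-11). The peaks at rpl-15 (signal 866, rank 24), rpl-3 (839, rank 29), rpl-35 (627, rank 60) and rps-1 (426, rank 169) were all without CACGTG, and 2 of the 32 distinct peaks of this list had it (6.25%). Mitochondrial ribosomal protein genes were bound at 5 of 66 (7.58%, adjusted exact p = 0.510), with mrpl-23 (199.8) the strongest. Without replicate 2 they stood at 1.52% and passed the test with fewer bound (adjusted exact p = 0.0207), and without replicate 1 at 9.09% they did not (adjusted exact p = 0.777). Body wall muscle markers were bound at 9 of 24 (37.5%, 18.8 to 59.4%, adjusted exact p = 0.0038), with unc-112 (269), act-2 (257), unc-60 (172) and act-4 (167) the strongest.

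The remaining lists did not pass the test. Other tissue markers were bound at 5 of 25 genes for intestine (20%, adjusted exact p = 0.334, rme-1 the strongest), 6 of 25 for hypodermis (24%, adjusted exact p = 0.122, vab-10), 1 of 17 for pharynx (5.88%, adjusted exact p = 0.743, pha-4), 1 of 32 for neurons (3.13%, adjusted exact p = 0.383, snb-1) and 1 of 35 for germline (2.86%, adjusted exact p = 0.323, spo-11). TOR and AMPK signalling genes were bound at 4 of 21 (19.05%, adjusted exact p = 0.407, aak-2 the strongest with 236), insulin signalling genes at 2 of 49 (4.08%, adjusted exact p = 0.323, ins-39 and akt-2) and glycolysis genes at 3 of 19 (15.8%, adjusted exact p = 0.510, hxk-3, aldo-2 and hxk-1). Aminoacyl-tRNA synthetases stood at 5 of 31 (16.13%, adjusted exact p = 0.510, hars-1 the strongest with 566), the proteasome at 5 of 33 (15.2%, adjusted exact p = 0.510, pbs-1 with 401), histones at 10 of 72 (13.9%, adjusted exact p = 0.510, his-37 with 686), collagens at 18 of 174 (10.3%, adjusted exact p = 0.810, col-65 with 262) and basic helix-loop-helix genes, the Max network included, at 7 of 40 (17.5%, adjusted exact p = 0.336, hlh-11 with 481 the strongest outside that network). Without replicate 1 the share was 12% for intestine, 26.3% for glycolysis and 5.88% for pharynx, and without replicate 2 it was 16%, 21.1% and 11.8%, none past the threshold. With each peak assigned to its nearest start within 2000 bp, in place of the promoter window, intestine (32%), hypodermis (36%) and collagens (18.4%) passed the test with more bound (adjusted exact p = 0.02003, 0.0073 and 0.0440). The change of rule and the change of distance were not separated.

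**Figure D4:**
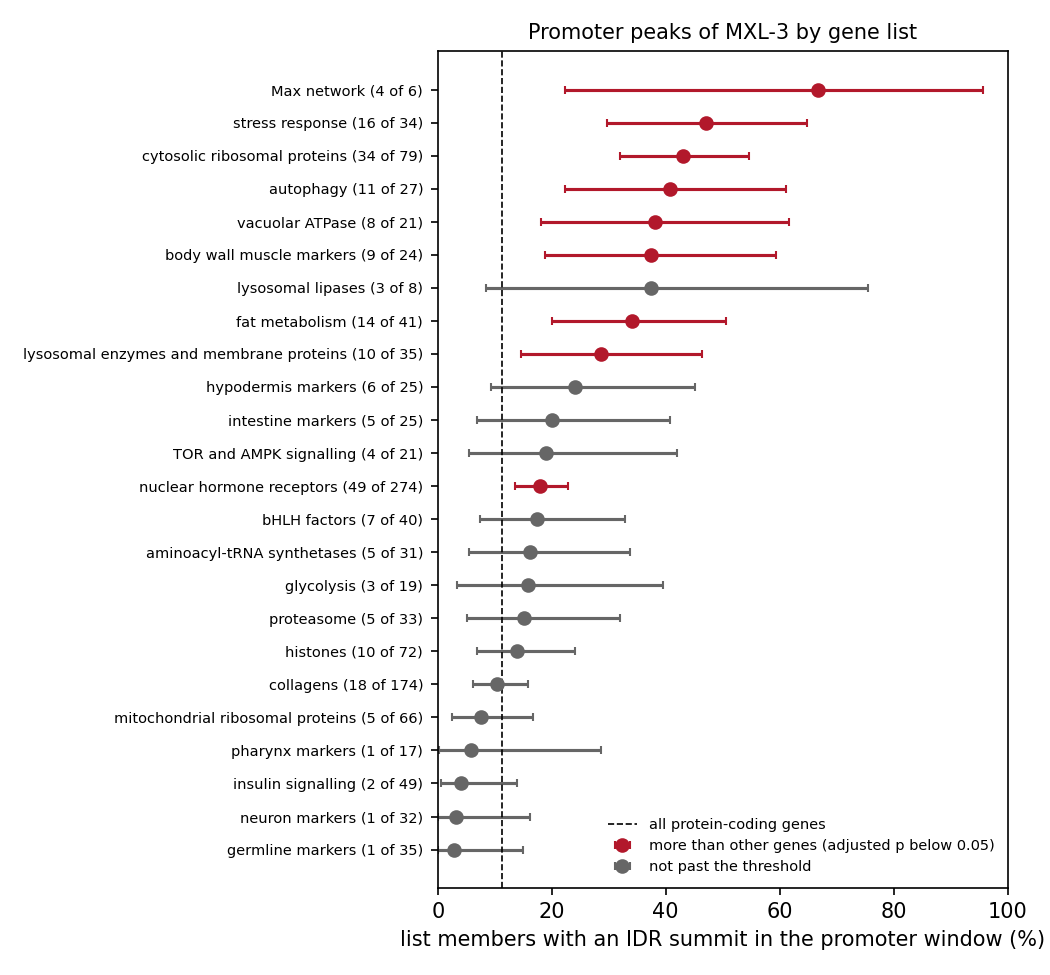
Percentage of the members of each gene list with an IDR summit in the promoter window (x axis), with exact 95% intervals as bars and the counts beside each list name. Red lists passed the test against other genes and grey lists did not, and the dashed line marks the 11.3% of all protein-coding genes.

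Fisher's test takes genes as independent, and 23 genes were in more than 1 list. Each list was set against all other protein-coding genes, active or not. Gene activity was not measured, so the lists were not compared with equally active genes. CACGTG lay at 1 of 15 distinct peaks for fat metabolism, 2 of 15 for stress response and 0 of 9 for body wall muscle. It lay at 3 of 13 for autophagy, 3 of 10 for lysosomal enzymes, 12 of 53 for nuclear hormone receptors and 1 of 4 for the Max network. A test that rotated the bound status of genes along the genome, added after the data were seen, kept all 9 calls, the largest adjusted p among them being 0.0272. With the stronger of 2 equal parts of the IDR list, the calls for lysosomal enzymes and membrane proteins, fat metabolism, nuclear hormone receptors and body wall muscle were lost (adjusted exact p = 0.122, 0.0909, 0.0807 and 0.122), and 5 lists passed. Over 13 alternatives these 4 lists passed in 10, 10, 10 and 11, with adjusted exact or rotation p up to 0.186, 0.995, 0.0807 and 1. These counts include the same number of pooled peaks, which is the IDR list itself and could not change a call. Counted with CACGTG peaks alone, which are fewer, 0 lists passed.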

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

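Of the tests below, the counts of pooled summits and of summits without CACGTG around mxl-3, the X share of peaks below the threshold and the CACGTG share of those peaks were chosen after the result was seen. The criteria of 2 tests were also made stricter then, as said beside each. The study has 1 group and no contrast between conditions, so binding at CACGTG sites was the only biological explanation tested.

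Peaks that the authors' threshold left out still carried CACGTG above the flanking sequence. Of the 26065 pooled peaks below the threshold, 6.78% (6.48 to 7.09%) had it within 100 bp of the summit and 3.45% had it in the flank (exact McNemar test, two-sided, p = 1.3e-68). Hexamers with the same bases were not compared in these peaks, so a part played by base composition stays open.

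Strong peaks crowded around mxl-3, the tagged gene, and extra copies of the locus on the transgene are a candidate source. The window within 20 kb of the gene held 37 pooled summits, against a median of 14 and a 99th percentile of 29 over 2716 equal windows on X, with a highest of 38, which met the bound set for extra copies. The IDR peaks are part of that count, so summits below the threshold were required to stand out as well, and the 17 of them were under the 99th percentile of 25 for such windows (median 12), so extra copies cannot be told apart from binding. CACGTG lay at 30% of the 20 IDR summits there (11.9 to 54.3%) and at 15.8% of the others (Fisher's exact test, two-sided, p = 0.115), which leaves open whether the share was higher. The 14 IDR summits without CACGTG were above every one of the other windows (median 2, 99th percentile 7, highest 9), so CACGTG sites do not account for all of the crowding.

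No explanation tested accounted alone for the excess of peaks on X. More CACGTG sites on X could give all of it only if peaks without the hexamer showed none. The X share of those peaks was 25.05% (23.6 to 26.6%) against 17.7% of genome length. CACGTG sites are thus not its only source, and whether they give a part was not tested. Without the peaks near mxl-3 the X share of IDR summits was 24.1% (22.8 to 25.5%), wholly above that length share. Pooled peaks below the threshold had 20.2% on X (19.7 to 20.7%), under the interval of the IDR peaks, so a tilt of the whole list could account for a part and not for all of it. A higher copy number of X than of other chromosomes relative to the control stays open and was not tested.

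Peaks at cytosolic ribosomal protein genes and tRNA genes formed a set of 221 summits that mostly lacked CACGTG. CACGTG lay at 3.17% of them (1.28 to 6.42%) and at 16.6% of the other IDR summits (Fisher's exact test, two-sided, p = 1.0e-09), so binding at that hexamer is unlikely to be their source. Of these summits 71.5% (65.1 to 77.3%) were among the 3935 highest-ranked peaks of both replicates. That was under the bound of 80% set beforehand for signal seen in one replicate list only, but the other IDR summits stood at 71.1%, so the bound was poorly chosen and, contrary to its wording, was not taken as a decision. Whether such highly transcribed genes attract signal without the tagged factor stays open, since no untagged strain was analysed here.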

How the results depend on the processing

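The rotation test, the mxl-3 and small RNA gene exclusions, the most upstream start and the pooled peaks below the threshold were added after the data were seen. Of 76 alternative values of the tests and counts other than single lists, 69 kept their direction and side of the threshold, or their size within 1.5 times for a count, which for the E-box classes called ranged from 4 to 7 with changed members, CAGATG the one gained, and the same number of pooled peaks changed nothing since that list is identical. Overlap and correlation of the replicates have no value without either replicate. The correlation rose to 0.734 in the stronger part of the IDR list and 0.748 at 50 bp. T before CACGTG passed the threshold in that stronger part (35.01%), at 50 bp (32.5%) and, leaving out a replicate, ranged from 36 to 36.6%. Lists called numbered 5 in the stronger part and 0 with CACGTG peaks alone. For single lists 269 of 312 values were unchanged in direction and call, and the cause of the changes was not tested, except that the stronger part and the sets by CACGTG hold fewer peaks. The 269 and the 69 both include values from the same number of pooled peaks, which could not differ. In the stronger part calls ended for lysosomal enzymes (14.3% bound), fat metabolism (14.6%), nuclear receptors (9.49%) and muscle (16.7%), and direction turned for glycolysis (5.26%), histones (5.56%), intestine (4%) and hypodermis (4%). Fat metabolism lost its call with the 500 bp promoter (19.5%), Max network without the mxl-3 locus (50%) and vacuolar ATPase with nearest starts (28.6%). Nearest starts also turned proteasome (12.1%), histones (9.72%) and collagens (18.4%). They added calls for collagens, intestine (32%) and hypodermis (36%), and the 2000 bp promoter turned histones (15.3%). With CACGTG peaks alone Max network (16.7%), autophagy (11.1%), lysosomal enzymes (8.57%), fat metabolism (2.44%), ribosomal proteins (2.53%), nuclear receptors (4.38%) and stress (5.88%) lost their calls, and direction turned for vacuolar ATPase, TOR, proteasome, intestine, muscle and hypodermis (0% each) and histones (1.39%). Without CACGTG peaks Max network (50%), lysosomal enzymes (20%) and nuclear receptors (14.2%) lost theirs, and glycolysis (5.26%), aminoacyl-tRNA synthetases (9.68%) and collagens (10.3%) turned. The most upstream start turned glycolysis (5.26%), collagens (10.3%) and hypodermis (8%). Leaving out a replicate ranged from 1.52 to 9.09% for mitochondrial ribosomal proteins, 10.3 to 11.5% for collagens, 5.88 to 11.8% for pharynx, 21.1 to 26.3% for glycolysis and 12 to 16% for intestine. Unknown depth limits what absence of a peak can show.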

Other observations

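The comparisons of gene classes, small RNA genes and hexamers in this part were chosen after the data were seen. Several chemoreceptor classes had few MXL-3 promoter peaks. Among 94 classes of at least 20 genes sharing a name, 14 were bound less often than other genes and 12 more often (Fisher's exact test, two-sided, Benjamini-Hochberg). The chemoreceptor classes str (0 of 193), srw (0 of 109), srbc (0 of 71), srg (0 of 61) and srt (0 of 61) had no bound member, and srh had 6 of 220 (2.73%, adjusted exact p = 7.5e-05). The C-type lectin class clec had 12 of 240 (5%, adjusted exact p = 0.0075). More often bound were the nuclear hormone receptor class nhr (48 of 269, 17.8%, adjusted exact p = 0.0094), which did not pass the rotation test (adjusted p = 0.0550), the lin class, named for cell lineage defects (22 of 47, 46.8%, adjusted exact p = 5.6e-08), hsp (9 of 22, 40.9%, adjusted exact p = 0.0050) and the DnaJ chaperone class dnj (9 of 29, 31.0%, adjusted exact p = 0.0179). With the rotation test 10 classes remained past the threshold as less and 6 as more often bound, and the F-box classes fbxa and fbxb were not among them.

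Genes for tRNA, snoRNA and snRNA were frequent sites, and piRNA genes were not. Within 100 bp of 1 of the 612 tRNA genes lay 189 IDR summits (4.803%, 4.16 to 5.52%), where that sequence is 0.164% of the genome, at 201 of the genes, and at most 21 summits lay there in 100000 random draws (permutation p = 1e-05, the smallest the draws can give). CACGTG was at 5 of the 189 summits (2.65%). The snoRNA genes had 76 summits (1.93%) and the snRNA genes 20 (0.508%), and miRNA genes had 5 (0.127%, permutation p = 0.186), not past the threshold. The 15363 piRNA genes had 16 summits (0.407%), where their sequence is 2.21% of the genome (permutation p for fewer = 1e-05, the smallest the draws can give). Of the tRNA summits 48.7% were on X, as were 45.1% of tRNA genes.

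Sequences other than the E-box were more common at summits. Of 2080 hexamers 966 were higher and 592 lower at summits than in flanks (exact McNemar test, Benjamini-Hochberg), with A and T rich hexamers prominent among the lower. GAGAGA lay at 42.7% of summits and 10.4% of flanks, AGAGAC at 29.8% and 6.79%, ACACAC at 27.04% and 7.32%, and GACGCA at 20.1% and 3.63%. Summits held more G or C than flanks, which alone moves such shares, and these 4 hexamers were not compared with others of the same bases. Any of the 6 enriched E-boxes lay at 52.1% of summits and 29.7% of flanks, so 1884 IDR peaks had none within 100 bp. The 6 had been chosen as higher at these same summits than in these flanks, so this difference is not a further test. They include CACCTG and CAGCTG, whose ratios were near the medians of hexamers with the same bases.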
